A study of Mus musculus with 8 samples.

How the data were processed

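RNA of gamma-delta T cells sorted in bulk from mouse spleen was measured by RNA sequencing in 8 libraries, 4 labelled infected and 4 labelled uninfected. Per the labels' protocols, the cells were sorted into RNAprotect reagent and RNA was extracted with RNeasy Plus Micro columns. Ribosomal RNA was then depleted with RiboGone, and stranded libraries were made with the SMARTer kit. Random-primed, ribosome-depleted libraries of this kind also read RNA without a poly-A tail, such as histone transcripts and small nucleolar RNA. Per the submitters' processing notes, FastQC 0.11.4, STAR 2.4.2a, Cufflinks 2.2.1 and the mouse build mm9 were used. The annotation and the use of strand are not given in the sources used here. The authors deposited 1 table of FPKM, a fragment value scaled to transcript length and to mapped fragments, with 23946 gene symbols and a column for each of the 8 libraries. FPKM divides by the length of the transcript model and by the library's depth. The number of fragments behind a value is therefore unknown, and no interval or detection floor that needs it is given. All columns were matched to a sample by the initial of the group and the number in the sample titles, and 0 per-sample columns were left unused. The table held no negative values and no repeated symbols, 9507 genes were at 0 in every library, and 0 of the 28 pairs of libraries held identical values. The mouse annotation at hand is of a later build than mm9, so no coordinates are given.

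Groups were taken from the titles and the infection status in the labels. The labels attach the parasite strain and day 19 to the uninfected samples as well, read here as samples collected on the same day. Nothing in the labels says that the numbered samples came from separate mice, so p-values measure only the spread between these samples, which may be technical.

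FPKM values were used as deposited, without further scaling, on the scale log2(FPKM + 1). Fold changes on this scale understate the change of genes with low FPKM. Group means or single values in FPKM are given for most named genes, and the ratio of means for Csf1, Spp1 and Ifng. Genes with FPKM of at least 1 in at least 4 of the 8 libraries were tested, which left 9974. A gene that reached 1 FPKM only in the 4 libraries of a single group passed through that group alone, which fixed its direction. The test was limma 3.58.1 in R 4.3.3 (a linear model per gene with moderated variances that follow the mean, two-sided), with Benjamini-Hochberg adjustment over all tested genes and a call at an adjusted p below 0.05. Every adjusted p of a gene below comes from limma. An exact two-sided permutation test of the 4 against 4 values was added for Csf1.

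Gene lists were written before the data were examined, as were the test, the filter and the rule for named genes. Of the 30 lists, 26 had at least 4 tested members and were tested with camera (limma), which compares a list's fold changes with those of all other genes, with a preset correlation of 0.01 between members and adjustment over the lists. Beside it stand camera with a correlation estimated from the data, fry, which tests whether a list's own genes move on balance in one direction, and its mixed form, which tests for change in either direction. Neither form of fry compares a list with other genes. The lists of mitochondrially encoded transcripts and of gamma-delta T cell receptor segments matched 0 symbols of the table and were not analysed here. The rule names Csf1, Csf2, Ccl3, Ccl4, Ccl5, Ifng, Tnf, Il17a and Il10. It adds the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 FPKM in the higher group and no overlap between groups, leaving out small RNAs, histones and predicted genes. It also takes up to 4 members per list with the smallest adjusted p. Genes named outside the rule are said to be so, and a few genes that the rule takes are not reported here.

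An exact 0 in such a table can be a failed estimate or a low value. Cox17, needed by every respiring cell and chosen after its values were seen, was at 37.2 FPKM on average in the infected libraries. In uninfected 1 to 4 it was listed at 6.15, 1.99, 0 and 4.43, so its 0 stands beside low values and does not tell these apart. For genes with an exact 0 the values of single libraries are therefore given, and no fold against a group listed at 0. Globins, Klra receptors, Bcl2a1 genes, Cd200r genes, Tgtp2, histones and small RNAs belong to families with near-identical copies, and their values are uncertain because reads may be split between copies.

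The steps were tested on simulated data built on the real genes' means and spread, with 4 libraries in each group and 9490 genes in the test. Of 100 genes changed by 1 on the log2 scale 74% were called, and of 100 changed by 2, 97%. Of all calls, 3.93% were genes left unchanged. The changed genes were drawn only from those well above the floor in uninfected libraries. These shares therefore do not cover genes that are low there, such as Csf1. With the cell cycle list raised by 1, camera called it and 0 of the other lists. The simulated genes were drawn independently of each other, while correlations estimated within the real lists were 0.0287 to 0.671. The simulation therefore does not show how camera behaves with correlated members. Alternatives tried were pseudocounts of 0.1 and 0.5, no filter, a filter of 5 FPKM, median-of-ratios scaling, quantile normalization, equal sums of FPKM with and without small RNAs and histones, limma without the trend and with robust moderation, sample weights, the replicate number as a block, and leaving out each of the 8 libraries, with the filter of 4 libraries and, added after seeing the data, with a filter of 3.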

Results

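Gamma-delta T cells, a T cell lineage with a receptor of gamma and delta chains, were sorted from the spleens of C57BL/6J mice 19 days after infection with Plasmodium chabaudi chabaudi AJ, a rodent malaria parasite of the blood stage. Cells of uninfected mice were sorted as well, with 4 libraries in each group. The comparison asks how the total gamma-delta T cell pool of the spleen differed in infected mice. It asks in particular whether the pool carried the transcript of macrophage colony-stimulating factor, the product of Csf1, which the study's title names. The values are FPKM. The sum of FPKM was 318597 to 368854 in the infected libraries and 253589 to 329395 in the uninfected ones. Between 12361 and 12967 genes had a value above 0 in the infected libraries, against 11106 to 11624 in the uninfected ones. Values between 0 and 0.1 FPKM were listed for 709 to 1069 against 193 to 265 genes. The correlation of log2 values was 0.971 to 0.985 between infected libraries, 0.928 to 0.950 between uninfected ones and 0.772 to 0.824 across groups. Uninfected 3 lay apart from the other uninfected libraries on the second principal component, which held 8.84% of the variance against 72.4% for the first, on which the groups separated.

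On the log2(FPKM + 1) scale Csf1 rose more than any other tested gene. It stood at 456 ± 53.8 FPKM (SD, n = 4) in infected and 1.82 ± 0.518 (SD, n = 4) in uninfected libraries, a ratio of means of 251 and a log2 fold change of 7.35 ± 0.15 (SE), with an adjusted p of 4.14e-10. All 4 infected libraries lay above all 4 uninfected ones, and the exact two-sided permutation test gave p = 0.0286, the smallest that 70 arrangements allow. Leaving out small RNAs, the next largest rises were those of Ccl3, a macrophage-attracting chemokine, at 230 ± 22.4 against 1.20 ± 0.971 FPKM, and Spp1, which encodes osteopontin, at 123 ± 23.7 against 0.354 ± 0.0796, with log2 fold changes of 6.80 and 6.50. By the ratio of mean FPKM, Spp1 rose more than Csf1, at 348 against 251.

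Secreted factors moved in both directions. Of the 18 tested cytokine and chemokine genes, 9 rose, 7 fell and 2 did not pass, with the same counts adjusted over the list alone. Those that rose included the chemokines Ccl4 (70.1 ± 24.1 against 3.13 ± 4.13 FPKM, log2 fold change 4.49, adjusted p = 3.00e-05) and Ccl5 (4086 ± 574 against 504 ± 125, 3.04, 1.08e-06), as well as Ifng, the gene of interferon gamma (15.4 ± 4.35 against 5.74 ± 4.17, a ratio of means of 2.68, adjusted p = 0.0159). Csf2, which encodes the related factor GM-CSF, rose from 1.26, 0.234, 0 and 0 FPKM in the uninfected libraries to 3.05, 5.42, 3.73 and 5.14 in the infected ones (adjusted p = 1.78e-04). Il10 stood at 7.02, 4.29, 3.47 and 12.6 FPKM in infected libraries and was listed at 0 in all 4 uninfected ones (adjusted p = 2.61e-05). Tnf fell from 8.45 ± 2.68 to 0.590 ± 0.159 FPKM (log2 fold change -2.53) and Ltb, the gene of lymphotoxin beta, from 243 ± 47.8 to 20.2 ± 3.80 (-3.52). Il17a was listed at 0 in all 8 libraries. As a list the secreted factors did not stand apart from other genes, with a camera adjusted p of 0.50 and an adjusted p of 0.719 with an estimated correlation.

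**Figure D1:**
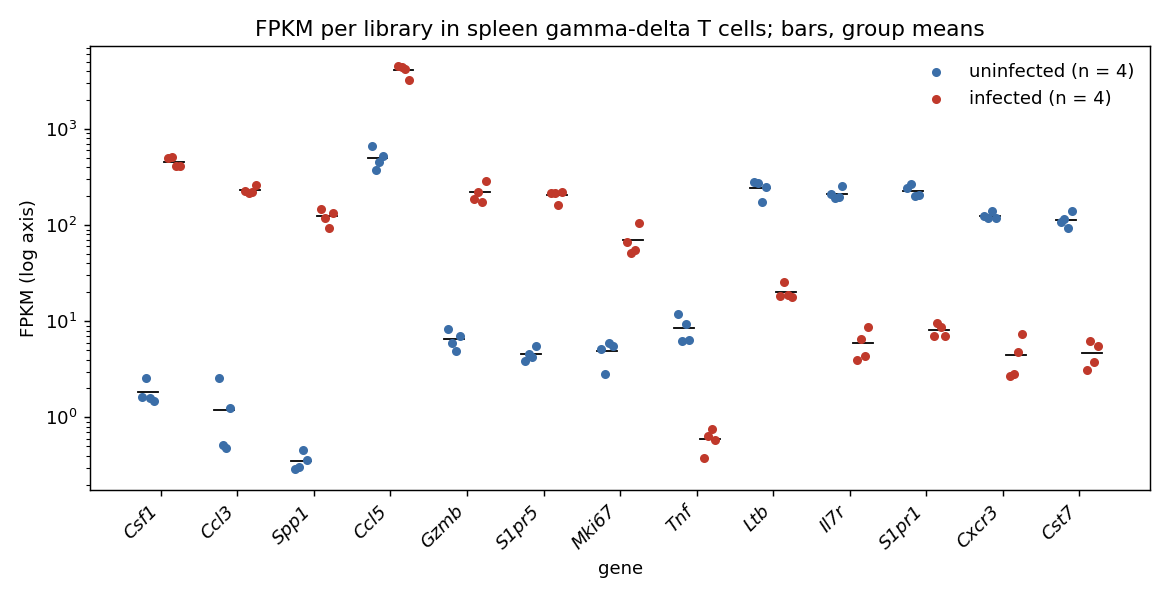
FPKM of 13 genes (log axis) in each of the 4 uninfected (blue) and 4 infected (red) libraries, with bars at the group means. Csf1 is at 408 to 510 FPKM in the infected libraries and at 1.47 to 2.59 in the uninfected ones, while Il7r, S1pr1, Cxcr3 and Cst7 lie the other way.

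In all, 4012 of 9974 tested genes were called, 2243 higher and 1769 lower in infected libraries, and 1121 rose and 814 fell by at least 1 on the log2 scale. The groups did not overlap for 38.7% of tested genes, where chance gives 2.86%. With every library rescaled to the same sum of FPKM, the median log2 fold change of the genes tested both ways moved from 0.05 to -0.16 and the split became 1637 higher and 2966 lower, so that small changes near these medians depend on the scale. Of the 26 lists tested, camera called 7 higher and 7 lower, or 0 and 1 with an estimated correlation. Without uninfected 3 it called 7 and 3 of 25, or 7 and 6 of 26 where FPKM of at least 1 in 3 libraries was enough, a filter added after the data were seen. Beside Csf1, Ccl3 and Spp1, the largest rises, leaving out small RNAs, histones and predicted genes, were those of the globins Hba-a2 and Hbb-b1 and of Slc17a6, a vesicular glutamate transporter (61.8 ± 19.1 against 0.292 ± 0.205 FPKM, log2 fold change 5.57). Smoc2, a secreted matrix protein (5.36), followed, with the Fc receptor-like gene Fcrl6 (5.23), Itgad, the integrin alpha D chain (190 ± 15.4 against 4.2 ± 0.893, 5.21), and Hbb-bt (5.21). Among the 10 largest falls were those of Il7r, the interleukin 7 receptor (5.89 ± 2.17 against 212 ± 28.7, -4.99), S1pr1 (8.13 ± 1.31 against 229 ± 30.7, -4.66) and Slfn5 (-4.66). Further ones were those of Cxcr3 (4.42 ± 2.15 against 125 ± 10.8, -4.62), Tgtp2 (-4.53), the sialyltransferase gene St6gal1 (-4.52), Nsg2 (-4.48) and Kbtbd11 (-4.47). Gpr15, a homing receptor, was at 0.325, 0.625, 0 and 0.334 FPKM in infected and 24.5 to 45.5 in uninfected libraries.

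Genes of naive and resting T cells fell throughout. All 19 tested members were lower, also adjusted over the list alone, with a median log2 fold change of -3.32 (camera adjusted p = 5.38e-20). The call was lost at an adjusted p = 0.124 with an estimated correlation. Alpha-beta T cell markers were mostly lower in the same libraries, with a median of -3.28 and Cd8a at 0.826 against 14.6 FPKM. Of these 6 markers 4 fell, 1 (Trat1) rose and 1 did not pass. The camera call of that list was lost too with an estimated correlation (adjusted p = 0.153). Beside S1pr1 the naive and resting genes that fell included Ccr7, a lymph node homing receptor (3.31 ± 0.772 against 76.6 ± 8.97 FPKM), and Il6st (2.42 ± 0.595 against 66.5 ± 3.76). The transcription factor genes Lef1 (3.65 against 75.3) and Tcf7 (66.9 against 442), chosen after their values were seen, fell as well. Migration and homing genes were mostly lower too: 17 of 23 fell and 5 rose, with the same counts adjusted over the list alone (median -2.93, camera adjusted p = 1.44e-06, adjusted p = 0.153 with an estimated correlation). Against that direction, S1pr5, a sphingosine-1-phosphate receptor, rose from 4.55 ± 0.687 to 204 ± 27.9 FPKM while the related S1pr1 fell.

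Of the 19 type 17 genes, those of interleukin 17-producing gamma-delta T cells, 12 were tested. All 12 fell, also adjusted over the list alone (median -2.46, camera adjusted p = 2.48e-11). This was the list whose call held with an estimated correlation (adjusted p = 0.0259). Without any single uninfected library fewer than 4 members passed the filter of 4 libraries, so the list was not tested. Its call held with the filter of 3. Members below 1 FPKM in every infected library, such as Ccr6, 5830411N06Rik and Rora, passed only through the uninfected libraries, which fixed their direction. The 12 falls and the camera call are therefore weak support, though the filter did not fix the size of each fall. The scavenger receptor gene 5830411N06Rik stood at 0.372 ± 0.0876 against 19.7 ± 4.07 FPKM and Rora at 0.599 ± 0.139 against 7.79 ± 0.651. Ccr6 stood at 0, 0.241, 0 and 0.136 in infected and 8.41 to 17.03 in uninfected libraries. In the type 1 list 9 of 19 members rose and 6 fell, also adjusted over the list alone, and camera made no call (adjusted p = 0.602; 0.725 with an estimated correlation). Its median of 0.24 and its mean of -0.07 differed in sign, and the median was -0.00374 with equal sums of FPKM. Prdm1 (51.2 ± 7.16 against 1.86 ± 0.429) and Zeb2 (45.1 ± 6.02 against 1.88 ± 0.441), transcription factors of effector lymphocytes, rose with Eomes (208 against 40.7, chosen after its values were seen). Cxcr3 and Il18r1 (1.42 ± 0.579 against 51.5 ± 14.4), receptors for chemokines and for interleukin 18, fell. Of the 15 innate-like and interleukin 4 programme genes 10 fell and 5 rose, also adjusted over the list alone (median -0.81, camera adjusted p = 0.0112, adjusted p = 0.277 with an estimated correlation). Slamf6 (2.96 ± 0.613 against 36.7 ± 7.85), Icos (0.572 ± 0.297 against 13.5 ± 1.40) and Zbtb16, the gene of the transcription factor PLZF (0.359 ± 0.141 against 7.57 ± 1.06), fell. Tox rose (97.3 against 35.7, chosen after its values were seen). This list's call was also lost without any single uninfected library, at adjusted p values of 0.0958, 0.0531, 0.102 and 0.0584 without uninfected 1, 2, 3 and 4, and was kept in these fits with the filter of 3 libraries.

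Cytotoxic and natural killer (NK) cell receptor genes moved both ways. Among 12 cytotoxic effectors 6 rose, 3 fell and 3 did not pass, also adjusted over the list alone (camera adjusted p = 0.521; 0.725 with an estimated correlation). Gzmb, the gene of granzyme B, rose from 6.59 ± 1.48 to 219 ± 52.6 FPKM and Fasl from 10.7 ± 2.09 to 44.0 ± 8.12. The cathepsin gene Ctsw fell from 94.9 ± 8.08 to 3.72 ± 0.973, and Cst7, which encodes the protease inhibitor cystatin F, from 114 ± 19.4 to 4.67 ± 1.47. The perforin gene Prf1, named after its values were seen, fell from 33.7 to 21.5. Of 20 NK cell receptor genes 11 rose and 7 fell, or 11 and 8 adjusted over the list alone (camera adjusted p = 0.366; 0.725 with an estimated correlation). Klre1 rose from 24.6 ± 7.29 to 378 ± 105 FPKM, Klra3 from 2.59 ± 0.796 to 106 ± 47.4, Klrb1f from 4.82 ± 1.32 to 56.4 ± 8.93 and Cd244 from 8.23 ± 2.25 to 84.1 ± 10.8. Ncr1, Klrb1c and Tyrobp, chosen after their values were seen, fell from 16.2 to 0.538, from 87.6 to 11.2 and from 9.89 to 0.812 FPKM.

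Of 21 activation and inhibitory receptor genes 10 fell and 8 rose, also adjusted over the list alone (camera adjusted p = 0.0565; 0.571 with an estimated correlation). The 4 with the smallest adjusted p fell: Cd6 (2.32 ± 0.317 against 50.5 ± 6.54 FPKM), Nt5e, the gene of the ectoenzyme CD73 (0.799 ± 0.172 against 26.3 ± 4.53), Cd5 (2.06 ± 0.666 against 54.8 ± 7.82) and the costimulatory receptor gene Cd28 (3.05 ± 1.09 against 70.2 ± 10.6). Of other members, chosen after their values were seen, Havcr2 (27.0 against 0.420), Tigit (72.7 against 5.21), Lag3 (22.8 against 3.67) and Pdcd1 (120 against 39.5) rose, and Btla (0.713 against 12.3) fell. In the immediate early list 6 of 25 genes rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.854; 0.924 with an estimated correlation; median -0.03, mean 0.05); with equal sums of FPKM 9 fell. Nr4a2 (105 ± 8.94 against 6.27 ± 2.11), Rgs1 (57.7 ± 9.69 against 8.54 ± 4.87) and Egr1 (63.4 ± 5.67 against 19.4 ± 5.64) rose, and Cd69, an early activation marker, fell (2.43 ± 0.756 against 37.2 ± 11.5).

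Cell cycle genes rose together. Of 37 tested, 36 were higher, also adjusted over the list alone (median 2.33, camera adjusted p = 1.79e-17, adjusted p = 0.153 with an estimated correlation). Mcm7, named after its values were seen, did not pass at 36.4 against 34.3 FPKM. Mki67, a marker of dividing cells, rose from 4.86 ± 1.37 to 69.7 ± 24.6 FPKM, Mcm6 from 43.4 ± 2.73 to 167 ± 18.8, Hmgb2 from 13.1 ± 3.02 to 72.1 ± 10.5 and Ccnb2, the gene of cyclin B2, from 1.71 ± 0.811 to 26.4 ± 5.89. Histone genes rose with them, 57 of 62, or 58 adjusted over the list alone (median 3.11, camera adjusted p = 1.55e-21, adjusted p = 0.153 with an estimated correlation). Among them were Hist1h1a (99.0 ± 11.5 against 10.9 ± 1.40), Hist1h1b (239 ± 27.5 against 14.8 ± 5.20), Hist2h2bb (963 ± 222 against 86.4 ± 18.7) and Hist1h2bn (741 ± 144 against 56.0 ± 16.7). Histones and small RNAs together made up 11.1% to 15.1% of all FPKM in infected and 3.79% to 4.99% in uninfected libraries. The globin gene Hbb-b1 was higher in the same libraries, at 437 against 9.29 FPKM.

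**Figure D2:**
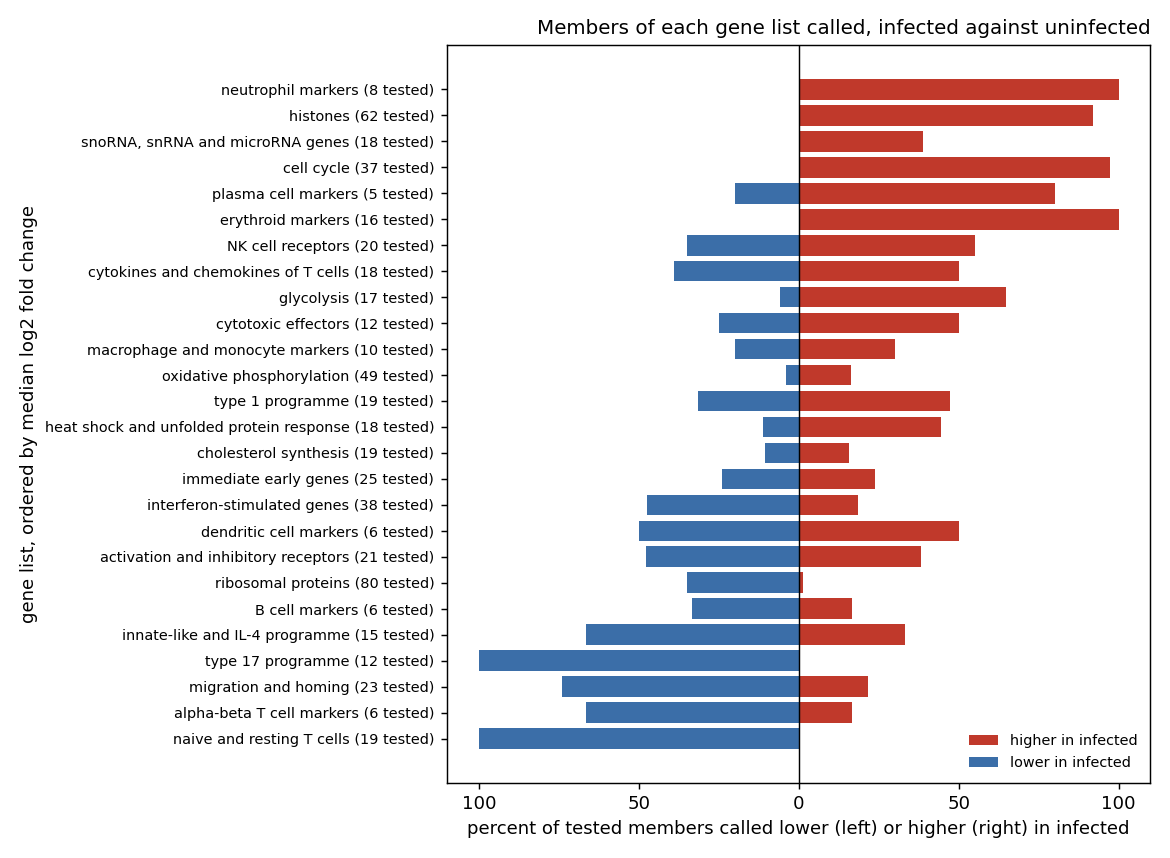
Percent of the tested members of each of 26 gene lists called higher (red, right) or lower (blue, left) in infected libraries by limma, with lists ordered by median log2 fold change. All 19 naive and resting and all 12 type 17 genes were called lower, and 36 of 37 cell cycle genes were called higher.

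Of 17 glycolysis genes 11 rose and 1, the glucose transporter gene Slc2a1, fell (8.01 against 17.3 FPKM, named after its values were seen), or 12 and 1 adjusted over the list alone (median 0.59, camera adjusted p = 0.00304, adjusted p = 0.339 with an estimated correlation). Quantile normalization and equal sums of FPKM left 9 that rose, with 1 and 2 that fell. Slc2a3, another glucose transporter gene, rose from 17.6 ± 3.16 to 133 ± 17.9 FPKM, Pfkp from 48.8 ± 2.96 to 105 ± 18.0, Ldha from 98.6 ± 9.66 to 187 ± 15.0 and Pkm from 85.1 ± 14.6 to 155 ± 18.6. Of 49 oxidative phosphorylation genes 8 rose and 2 fell, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.107; 0.725 with an estimated correlation). With quantile normalization 7 rose and 7 fell, with equal sums of FPKM 7 and 8, and with equal sums without small RNAs and histones 8 and 4. Ndufa1, Ndufa4, Cox6a1 and Atp5j rose by 1.22 to 1.47 on the log2 scale. Of 19 cholesterol genes 3 rose and 2 fell, or 1 and 2 adjusted over the list alone (camera adjusted p = 0.856; 0.938 with an estimated correlation). With equal sums of FPKM 1 rose and 3 fell. Stard4 rose (18.8 ± 2.78 against 7.29 ± 2.2) and Lss was among those that fell. Fdft1, at 0.63 ± 0.21 (adjusted p = 0.0326), lost its call without infected 1, 2 or 4 or uninfected 1 or 3 (adjusted p values of 0.0675, 0.0642, 0.0883, 0.0856 and 0.0724). It also lost it with no filter (0.0547) and with equal sums of FPKM (0.0928, log2 fold change 0.41). Of 18 heat shock and unfolded protein response genes 8 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.50; 0.725 with an estimated correlation). Their median was 0.09. It turned to -0.11 with quantile normalization, where 6 rose and 4 fell, and to -0.15 with equal sums of FPKM, where 5 rose and 5 fell. Hsp90b1, Pdia6 and Sdf2l1, chaperone genes of the endoplasmic reticulum, rose by 1.09 to 1.55 and Hsph1 fell by 0.88. Ribosomal protein genes fell in 28 of 80 cases and rose in 1, or 27 and 1 adjusted over the list alone (median -0.40, camera adjusted p = 3.08e-04, adjusted p = 0.719 with an estimated correlation). The number that fell was 42 with quantile normalization, 45 with equal sums of FPKM and 40 with equal sums without small RNAs and histones. Rps2 (308 ± 29.1 against 844 ± 209) and Rps18 fell. Rps27l rose, at 2.47 to 6.18 FPKM in infected libraries and 1.47, 0, 0 and 0 in uninfected ones. Of 18 tested small RNA genes 7 rose, also adjusted over the list alone (camera adjusted p = 0.00405, adjusted p = 0.238 with an estimated correlation). Rmrp stood at 4842 ± 994 against 439 ± 213 FPKM. Mir8104 was at 41.5 to 647 FPKM in infected libraries and at 35.1, 0, 0 and 0 in uninfected ones. Snora78 and Snora44 were at 21.5 to 88.6 and 51.9 to 430 in infected libraries and listed at 0 in all 4 uninfected ones.

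Interferon-stimulated genes leaned lower, with 18 of 38 that fell, 7 that rose and 13 that did not pass, also adjusted over the list alone (median -0.17, camera adjusted p = 0.0340, adjusted p = 0.617 with an estimated correlation). Ifit3 (2.61 ± 0.490 against 14.3 ± 2.27 FPKM) and Oas3 (6.59 ± 1.67 against 29.0 ± 5.15) fell. Rsad2 (17.2 ± 5.72 against 3.20 ± 0.426) and Oas1a (26.4 ± 5.52 against 9.16 ± 1.42) rose. The call was also lost with equal sums of FPKM (adjusted p = 0.0563, or 0.0525 without small RNAs and histones), with a filter of 5 FPKM (0.0533), without infected 2 (0.0678) and without uninfected 3 (0.0752).

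Markers of other blood cells moved as well. All 16 tested erythroid markers rose, also adjusted over the list alone (median 1.88, camera adjusted p = 2.67e-07, adjusted p = 0.238 with an estimated correlation). The globin Hba-a2 was at 252 ± 113 against 3.78 ± 2.87 FPKM, Hbb-b1 at 437 ± 214 against 9.29 ± 8.75 and Hbb-bt at 156 ± 27.2 against 3.75 ± 2.64, and Alas2, the erythroid enzyme of haem synthesis, at 32.3 ± 8.78 against 1.14 ± 1.09. All 8 tested neutrophil markers rose, also adjusted over the list alone (camera adjusted p = 1.38e-05, adjusted p = 0.238 with an estimated correlation). S100a8 was at 21.3, 26.9, 18.8 and 23.6 FPKM in infected libraries and listed at 0 in all 4 uninfected ones. It passed the filter only through the infected libraries, which fixed its direction. The granule protein genes Camp, Lcn2 and Ltf were at 7.59 to 21.7, 5.91 to 19.3 and 3.42 to 11.8 FPKM in infected libraries, and at 1.40, 1.52 and 0.565 in uninfected 1 and at most 0.116 in the other uninfected libraries. Of 10 macrophage and monocyte markers 3 rose and 2 fell, or 4 and 2 adjusted over the list alone (camera adjusted p = 0.512; 0.725 with an estimated correlation). With quantile normalization 2 rose and 2 fell. Cd68, a lysosomal protein gene, rose from 4.25 ± 2.57 to 100 ± 24.2 and Hmox1 from 3.60 ± 1.78 to 13.8 ± 3.77. Ccr2 fell from 11.4 ± 4.42 to 0.632 ± 0.675, and Lyz2, chosen after its values were seen, stood at 22.8 against 22.6. C1qb (1.10 to 1.54 FPKM in infected libraries; 1.30, 0, 0 and 0 in uninfected ones) was called at an adjusted p of 0.0237 and lost its call in 7 of the 8 fits that left out a library and with quantile normalization (0.0563).

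Of 6 alpha-beta T cell markers 4 fell and 1 rose, also adjusted over the list alone (median -3.28, camera adjusted p = 0.00924, adjusted p = 0.153 with an estimated correlation; adjusted p = 0.0752 without uninfected 3, where the call was kept with the filter of 3 libraries). Themis (6.92 ± 0.908 against 88.4 ± 18.4 FPKM) and Cd8a (0.826 ± 0.190 against 14.6 ± 2.35) fell. Cd40lg was at 0.0950, 0.198, 0 and 0.208 in infected and 8.17 to 15.0 in uninfected libraries. Trat1, which encodes an adaptor bound to the T cell receptor, rose (516 ± 84.3 against 61.1 ± 6.48). Of 6 B cell markers 2 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.350; 0.719 with an estimated correlation). Cd22 rose (20.4 ± 2.62 against 3.80 ± 0.813), Cd79b and H2-Eb1 fell, and H2-Ab1 did not pass at 5.99 ± 1.75 against 9.74 ± 3.76 (adjusted p = 0.0852). It passed as lower with equal sums of FPKM (0.0249) and without infected 2 (0.0482). Of 5 plasma cell markers 4 rose and 1 fell, also adjusted over the list alone (median 1.94, camera adjusted p = 0.0170, adjusted p = 0.238 with an estimated correlation). The 4 were Prdm1, which is also in the type 1 list, Irf4 (8.14 ± 0.542 against 1.51 ± 0.906), Igj (6.18 to 9.11 FPKM in infected libraries; 0.859, 0, 0.342 and 0.176 in uninfected ones) and Slpi (1.37 to 2.30, and listed at 0 in all 4 uninfected libraries). Sdc1, the plasma cell surface marker, named after its values were seen, fell, at 0.193, 0.103, 0 and 0.325 FPKM in infected libraries and 1.21 to 2.75 in uninfected ones. Of 6 dendritic cell markers 3 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.552; 0.725 with an estimated correlation). Itgax, an integrin gene, was at 60.3 ± 6.23 against 3.22 ± 0.685, Irf8 at 17.8 ± 2.11 against 6.86 ± 1.84 and Ccr9 at 1.72 ± 0.590 against 44.0 ± 3.23. Of 2 tested platelet markers Itgb3 fell (4.80 ± 1.30 against 38.6 ± 2.35) and Ppbp did not pass over all genes (adjusted p = 0.0906), though 1 of them rose and 1 fell adjusted over the list alone. Ppbp was at 1.14 to 3.31 FPKM in infected libraries and 3.85, 0.434, 0 and 0 in uninfected ones, and passed as higher without uninfected 1 (adjusted p = 0.00167). Pecam1, the 1 tested marker of stroma and endothelium, fell (2.09 ± 0.567 against 43.0 ± 1.15), also adjusted over the list alone.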

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

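The search for outlying libraries was planned, and all genes of the signalling, surface molecule, apoptosis and transcription factor groups in it, with Tox and Slc4a1, were chosen after their values were seen. In each group of 4 libraries, a library was singled out where its gap to the nearest of the others was a large part of the group's range. For normally distributed values chance flags about 1 in 20 groups. That rate need not hold for FPKM, used here without logs, and a group with a single library above 0 is always flagged. Of the 341 groups 33 held such a library: infected 4 in 9, uninfected 1 in 7, uninfected 2 in 5, uninfected 3 in 4, infected 2 in 3, infected 1 and infected 3 in 2 each and uninfected 4 in 1. No explanation was tested for these values.

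Infected 4 stood below the other infected libraries for Hbb-bt at 116 FPKM (others 166 to 175) and 5830411N06Rik at 0.241, and above them for Klre1 at 535 (others 312 to 334), Cd28 at 4.68, Pfkp at 131, Ccr2 at 1.64, Lat2 at 104 and Tox at 107. Its 10 highest genes held 15.96% of all FPKM (others 18.7% to 18.8%). Infected 1 was low for Nsg2 at 2.72 and Cd2 at 40.3. Infected 2 was high for Ltb at 25.9, H2-Ab1 at 8.58 and Mir8104 at 647 (others 41.5 to 100.4). Infected 3 was low for S1pr5 at 162 and high for Snora44 at 430 (others 51.9 to 112).

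Uninfected 1 was above the other uninfected libraries for C1qb at 1.30, Camp at 1.40, Lcn2 at 1.52, Rps27l at 1.47 and Mir8104 at 35.1, all listed at 0 in the other uninfected libraries. It was also above them for Ppbp at 3.85 and Thy1 at 326. Uninfected 2 was high for Csf1 at 2.59 (others 1.47 to 1.62), Ccl4 at 9.29 (others 0.470 to 1.49), Pkm at 107 and Hic1 at 15.9, and low for Cd200r2 at 1.18. Uninfected 3 was low for Cd5 at 43.2 and high for Ccr6 at 17.03, Lss at 5.81 and Slc4a1 at 4.59. Uninfected 4 was low for Prdm1 at 1.22 (others 2.06 to 2.11).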

How the results depend on the processing

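All alternatives here were planned, apart from the filter of 3 libraries, which was chosen after seeing the data. The count of called genes was 3933 and 3993 with pseudocounts of 0.1 and 0.5, 4380 without a filter, and 3033 with a filter of 5 FPKM, against 4012. It was 4299 with median-of-ratios scaling, 4396 with quantile normalization, 4603 with equal sums of FPKM and 4228 with equal sums without small RNAs and histones. It was 3944 without the trend, 4024 with robust moderation, 4488 with sample weights, and 3022 to 3735 leaving out a library. Equal sums of FPKM raised the number of genes called lower to 2966. Csf1 was called under each of these alternatives, with a log2 fold change of 7.30 to 7.47 leaving out a library. With the replicate number as a block, 4374 genes and 14 lists were called and Csf1 stood at 7.35. Correlations of deviations between samples of the same number were -0.06, 0.16, -0.06 and 0.25, and 4 of the 8 samples correlated best with the sample of their own number. These values do not settle whether the numbers pair the samples. The numbers were not treated as pairs because nothing in the labels says that they are. The called lists, 14 in all, became 1 with an estimated correlation (0 higher and 1 lower), 18 with directional fry and 26 with mixed fry, which ask other questions than camera. Leaving out a library gave 3 (without uninfected 3) to 7 lists called lower. Genes seen only in the smaller group of 3 could not reach the filter of 4 libraries there, so the type 17 list without an uninfected library and the plasma cell list without an infected one were not tested. With FPKM of at least 1 in 3 libraries, 3368 to 4115 genes and 6 to 8 lower lists were called, and type 17, plasma cell, innate-like and alpha-beta T cell lists kept their calls. The plasma cell list was not tested with a filter of 5 FPKM either, nor the histone and small RNA lists without those genes. Of 164 results of named genes other than Csf1, 2 lost a call (Fdft1 and C1qb) and 3 gained one (Ppbp, H2-Ab1 and Nkg7, the last lower with quantile normalization, adjusted p = 0.0132, and with equal sums of FPKM, 0.0172). Of 26 lists, 13 lost a call with an estimated correlation and 3 of these also elsewhere (interferon-stimulated, innate-like and alpha-beta T cell), without a reversed direction; with the filter of 3 libraries 1 did (interferon-stimulated; the cause was not tested). Calls were gained by the cytokine list without uninfected 1 (adjusted p = 0.0318) or uninfected 2 (0.0371), by oxidative phosphorylation without infected 1 (0.0389) or uninfected 1 (0.0406), by NK cell receptors with a filter of 5 FPKM (0.00635), and by activation receptors with that filter (0.0224) and with no filter (0.0404). With the filter of 3 libraries the cytokine list gained none, while activation receptors did without infected 1 (0.0468), infected 3 (0.0470) or uninfected 4 (0.0422) and oxidative phosphorylation without uninfected 1 (0.0258). FPKM without counts leave the depth unknown.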

Other observations

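The genes of the first 2 paragraphs, Klrb1b, Slc4a1, the single NK markers other than Klre1, and the comparison of summed cell cycle and globin values, were chosen after the results were seen; the other tests were planned. The adaptor gene Lat2 stood at 98.5 ± 3.83 FPKM (SD, n = 4) against 7.16 ± 1.51, Plcg2 at 63.7 ± 2.59 against 3.97 ± 1.39, Pik3ap1 at 115 ± 12.9 against 8.39 ± 1.97 and the inhibitory receptor gene Lair1 at 56.5 ± 13.4 against 5.99 ± 2.29. Cd200r1, Cd200r2 and Cd200r4, whose near-identical copies leave single values uncertain, rose by 2.72, 4.09 and 2.90 on the log2 scale. Among surface molecules of T cells, Cd7 rose from 274 ± 17.3 to 2377 ± 212 FPKM, while Cd2 fell from 333 ± 36.8 to 58.4 ± 12.2, Thy1 from 274 ± 35.2 to 47.7 ± 20.3, Cd37 from 114 ± 16.7 to 11.6 ± 2.12 and Dpp4 from 61.0 ± 7.00 to 5.78 ± 0.868.

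The survival genes Bcl2a1b and Bcl2a1d, near-identical copies, rose by 3.73 and 4.28 on the log2 scale. Tnfsf10, which encodes the death ligand TRAIL, rose too (190 ± 32.3 against 46.6 ± 3.64 FPKM). The transcription factor genes Hic1 (103 ± 20.2 against 10.5 ± 3.63), Prdm16 (96.7 ± 6.89 against 12.1 ± 2.68) and Bhlhe40 (54.3 ± 7.71 against 8.02 ± 1.47) rose, and Myb (3.39 ± 0.422 against 52.2 ± 5.43) and Sox4 (2.96 ± 0.575 against 23.0 ± 2.23) fell. Csf1r, the receptor gene for the Csf1 product, was below the filter at 0.669 ± 0.163 against 0.908 ± 0.555 FPKM.

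The 4012 called genes were set against chance and depth. Of the 35 splits of the 8 samples into 4 and 4, 1, the real one, gave as many genes (the highest other gave 1) and 1, again the real one, gave as many lists (14 against 12 in the highest other). Every other split put libraries of both groups on each side, which widens the spread within a side. Few called genes there were therefore fixed in advance. With 35 splits of samples that may not be separate mice, chance cannot be excluded for either count. Each of the 18 splits with 2 infected libraries on each side called 2 to 5 lists with 0 genes called, and the other 16 called 7 to 12. Camera at the preset correlation thus called at least 2 lists even where the groups were balanced. Since these splits also mix the groups on each side, their counts do not measure false calls in the real comparison. A list call alone is still weak evidence, as 13 of the 14 were lost with an estimated correlation. A lower depth of the uninfected libraries, which list fewer genes above 0, could move genes near the floor, but 45.1% of the 2964 tested genes with a mean of at least 20 FPKM were called, which argues against depth as the whole cause.

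Gzmb, Klra3, Klrb1b and S1pr5, genes that NK cells also use, were higher in the infected libraries. NK cells sorted along with the gamma-delta T cells could raise them, although the sort for these cells should remove NK cells. Over 13 NK markers written down beforehand, 11 of them held by another list and all 13 at an uninfected mean of at least 1 FPKM, the median log2 fold change was -0.25, with 6 higher and 6 lower (Ncr1, Klrb1c, Tyrobp and Fcer1g among these), while the CD3 chains had a median of 1.05 (-0.04 to 1.71), or 0.81 without Cd247, which NK cells also express and which was left out after the values were seen. The most abundant NK markers in infected libraries were Klre1 (378 against 24.6 FPKM), Eomes (208 against 40.7), Gzma (203 against 26.8) and Nkg7 (159 against 192). Klre1, Eomes and Gzma rose, as NK cells would also make them. The fall of Ncr1, Klrb1c, Tyrobp and Fcer1g, and the CD3 chains, of which 3 of 4 rose, argue against NK cells as the source. A difference of the gamma-delta T cell pool itself stays open as a hypothesis. A bulk sort does not show whether such a difference lay within cells.

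Globins were higher in the infected libraries, and red cells or their precursors carried over from infected spleens could bring them, although a sort for gamma-delta T cells should remove these cells. The 17 non-globin erythroid markers that reached 1 FPKM, of which 0 are in another list and 4 had an uninfected mean of at least 1, had a median log2 fold change of 1.51 (-0.22 to 4.05) and 16 were higher. Alas2 was at 32.3 against 1.14 FPKM and Slc4a1 at 30.0 against 1.40, which is consistent with carry-over of red cell RNA. Dividing red cell precursors could then also add to the cell cycle genes, whose summed rise in infected 1 to 4 was 763, 622, 564 and 1048 FPKM, while that of the listed globins was 710, 1095, 1106 and 454 (ratios of 0.510 to 2.31). By size the comparison did not decide, since the globin rise was the larger in infected 2 and 3 and the cell cycle rise in infected 1 and 4. The orders of these rises over the infected libraries were opposite, which was not tested. Infected 4 had the largest cell cycle rise and the smallest globin rise, and infected 3 the reverse. Had the same cells brought most of both, the rises would run in the same order. The values thus argue against globin-making precursors as the main source in these 4 libraries. Whether precursors added a part of the cell cycle rise cannot be told here.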
